A study of Homo sapiens with 20 samples.

How the data were processed

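Accessible chromatin was profiled by ATAC-seq in 20 libraries of MCF-7 cells, 2 for each of 10 groups. In this assay the Tn5 transposase cuts open chromatin and inserts sequencing adapters there, so that the number of reads at a site reflects its accessibility. The groups were untreated cells at 0 h and cells kept for 1, 8 or 24 h in medium with ethanol (0.1%, the vehicle), menadione (10 µM) or tert-butyl hydroperoxide (80 µM).

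The deposited table holds raw counts of reads for each of 73493 peaks in each of the 20 libraries, with no normalization. Per the submitters' processing notes, the build was hg19 and the tools were CASAVA 1.8.2, Bowtie2 2.2, SAMtools 1.2 and 1.9, Picard, MACS2 2.1, bedtools 2.27.1 and deepTools 3.3.0. These notes give no role or order of the tools. Per the file headers, mitochondrial reads and duplicates were removed before counting, runs were merged, and reads carried a mark for the Tn5 adjustment, whose size is not given in the sources used here. The peak set joins, per the name of the deposited file, peaks kept by an irreproducible discovery rate (IDR) step, which retains peaks ranked alike in replicates. Each joined peak lists the conditions it came from, so peak calls exist per condition and not per library. Because duplicates were removed, the highest peaks of the deepest libraries may have lost true repeat cuts. Whether repeated or amplified regions were filtered out (a blacklist) is not given in the sources used here. Peaks were fixed over all conditions before counting, so the same regions were compared in every library.

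Each group had 1 count column with the letter A and 1 with the letter E, which are called the A and E library series here. The columns carry no replicate number, so a column was tied to its group and not to 1 of the 2 labelled replicates. Nothing in the labels says that the 2 replicates of a group were separate cultures, and p-values then measure only the spread between these samples, which may be technical. No group held 1 library under 2 names, since chi-square per degree of freedom between its 2 libraries was 2.32 to 4.57. The letters were treated as a technical batch. Libraries of the same series deviated together from their group means with a correlation across peaks of 0.013 to 0.33 over the 45 pairs of groups (mean 0.14, above 0 in 45 and above 0.1 in 24). A fit with the series as an added term (a replicate block by library series) was therefore run beside each comparison and is named as an alternative chosen after seeing the data.

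Total counts over the peaks ran from 3.52 to 5.37 M (1e6 counts) in the A series and from 2.09 to 3.53 M in the E series. Peaks with little signal were removed with edgeR's filterByExpr, which left 72830 tested peaks. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with the robust quasi-likelihood F test, in 1 fit of all 20 libraries with a coefficient for each group and 10 residual degrees of freedom. All p-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested peaks of a comparison, and a call is an adjusted p under 0.05. Levels are given as counts per 1e6 counts (CPM, with TMM factors), as mean ± SD of 2 libraries, and effects as log2 fold changes with their standard errors (SE). Principal components used log2 CPM with a prior count of 2. DESeq2 1.42.0 was run as a second tool. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

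The comparisons were menadione or tert-butyl hydroperoxide against vehicle at each time, menadione against tert-butyl hydroperoxide at each time, vehicle against untreated cells, and for each oxidant an F test of whether its difference from vehicle changed between times. Chosen before the data were examined were these tests, the filter, the rule for named peaks and most alternatives. The rule named, for each oxidant against vehicle, the 3 called peaks with the largest rise and the 3 with the largest fall among peaks with a mean count of at least 50 whose 2 treated libraries both lay outside the vehicle libraries. For the other comparisons it named 5 of each. Called peaks outside the rule, and peaks called only with the series term, were chosen after their values were seen. So was everything that averages an oxidant over its 3 times. Location tests compared called peaks with all tested peaks by Fisher's exact test, or with 10000 random lists of the same size matched on mean count, adjusted over 54 tests.

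The pipeline was tested on simulated counts drawn from the real means, library sizes and spread, with 66 or 67 peaks changed at each of 3 sizes (1.5-fold, 2-fold and 4-fold) in each comparison. Without the series term, 4-fold changes were recovered in 45.5%, 33.3% and 42.4% of the changed peaks for menadione at 1, 8 and 24 h, and in 43.9%, 43.9% and 22.7% for tert-butyl hydroperoxide. For 2-fold changes these shares were 1.49%, 1.49%, 5.97%, 0%, 1.49% and 2.99%. With the series term, 4-fold changes were recovered in 51.5%, 50%, 65.2%, 56.1%, 60.6% and 47%. In 5 simulated data sets with no change, the 30 oxidant comparisons gave 0 calls without the series term and 11 with it. These 5 also gave the correlation, covariance and share of equal signs with shared vehicle libraries. A further 10 unchanged data sets gave the correlations within a series, the overlaps of calls and the calls of the tests between times. Counting intervals cover counting error only.

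No genome or annotation of hg19 was used here, since the gene table at hand follows another assembly (GRCh38.p14). Peaks are therefore given by hg19 coordinates, counted from 1, without gene names, motifs, base composition or distance to promoters. Alternatives were other scalings (DESeq2 size factors, library totals, loess offsets by mean accessibility), other filters (none, or a mean count of at least 50), fits of the contrasted groups alone, other thresholds, and each library left out in turn. Fits with a library left out had no series term, except those averaged over time. A group left with 1 library then held 1 series alone, so the difference between series entered its comparisons.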

Results

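MCF-7, an estrogen receptor-positive human breast cancer line, was exposed to 2 oxidants: menadione, a quinone that cycles between redox states, and tert-butyl hydroperoxide (TBOOH), an organic peroxide. Accessibility was read from 20 ATAC-seq libraries, with 2 libraries, 1 of the A and 1 of the E series, in each of 10 groups. The question of the series was whether cells answer oxidative stress within a set of accessible regions that exists beforehand. Total counts over the 73493 peaks were 3.52 to 5.37 M in the A series and 2.09 to 3.53 M in the E series (M, 1e6 counts). Within each time and series, the oxidant library had a lower total count than the vehicle library in 12 of 12 pairs, so depth and oxidant treatment ran together. Peaks had a median width of 533 bp and covered 24 chromosomes.

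Much of the accessible landscape was shared by the 10 conditions. The authors' peak lists placed 18530 peaks (25.2%) in all 10 conditions, and these held 60.5% of the counts, with a median width of 868 bp. Another 15421 peaks (21%) came from a single condition and had a median of the mean count of 10.8, against 83.8 for the peaks found in all conditions. Peaks listed only in oxidant conditions numbered 10920 (14.9%) and held 4.28% of the counts, while 10063 (13.7%) were listed only in vehicle or untreated cells and held 4.39%. The number of IDR peaks of a condition, 53021 for TBOOH at 1 h to 76114 for vehicle at 8 h, followed the total count of its 2 libraries. Over the 10 groups Pearson's r was 0.982 (permutation p = 1e-05, the smallest that 100000 resamples can give) and Spearman's rho was 0.964 (permutation p = 5e-05). Without the 2 groups farthest from the median depth r was 0.955. This was the only relation computed in its family, and no value within a series can be had because peaks were called per condition. A peak listed in a single condition is therefore no evidence of a change.

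With TBOOH, counts rose at a small set of regions within 1 h. Whether these reads came from 1 common source spread over similar sequences stayed open (see the other observations). Of 72830 tested peaks, 5 rose and 0 fell against vehicle (edgeR quasi-likelihood test, adjusted p under 0.05). The 2 largest rises lay about 5 kb apart on chromosome 14. At 14:35016962–35018342, accessibility was 63.2 ± 9.01 CPM with TBOOH and 6.56 ± 2.39 CPM with vehicle (SD, n = 2), a log2 fold change of 3.29 (SE 0.38, edgeR adjusted p = 2.9e-06). At 14:35023242–35024581 the values were 75.7 ± 3.3 and 8.57 ± 1.64 CPM (log2 fold change 3.15, SE 0.32, edgeR adjusted p = 1.3e-07). A peak of high accessibility, 1:210545228–210548049, rose from 51.4 ± 9.34 to 217 ± 15.8 CPM (log2 fold change 2.08, SE 0.27, edgeR adjusted p = 0.00013). The other 2 called peaks, named after their values were seen, were 3:112359161–112360202, at 53.3 ± 3.86 against 16.7 ± 0.662 CPM, and 1:149222422–149224291, at 280 ± 34.1 against 93 ± 2.66 CPM. In untreated cells the peak 1:210545228–210548049 had 44.7 ± 7.03 CPM and 1:149222422–149224291 had 98 ± 0.686 CPM. Both were IDR peaks in all 10 conditions. Untreated levels were 8.33 ± 4.41 CPM at 14:35016962–35018342, 16.5 ± 3.09 CPM at 14:35023242–35024581 and 16.6 ± 0.959 CPM at 3:112359161–112360202. These were IDR peaks in 4, 5 and 7 conditions. At 14:35023242–35024581 untreated lay above vehicle at 1 h, so the rise over untreated cells was smaller than that over vehicle.

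The fit with library series as a term kept these 5 and called 17 rises and 11 falls at 1 h, or 25 and 8 with loess offsets as well. Among its falls were 16:2059306–2060067 (log2 fold change −1.60, SE 0.35), 10:72147032–72147689 (−1.58, SE 0.34) and 6:27782424–27783304 (−1.47, SE 0.28, from 35.1 ± 4.13 to 12.6 ± 1.31 CPM), which had edgeR adjusted p = 0.046, 0.043 and 0.0097 there and 0.49, 0.48 and 0.35 without the term. DESeq2 called 8 peaks. The number of calls changed when either vehicle library at 1 h was left out. Vehicle was then left with 1 series alone in a fit without the series term, so the difference between series entered the comparison.

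**Figure D1:**
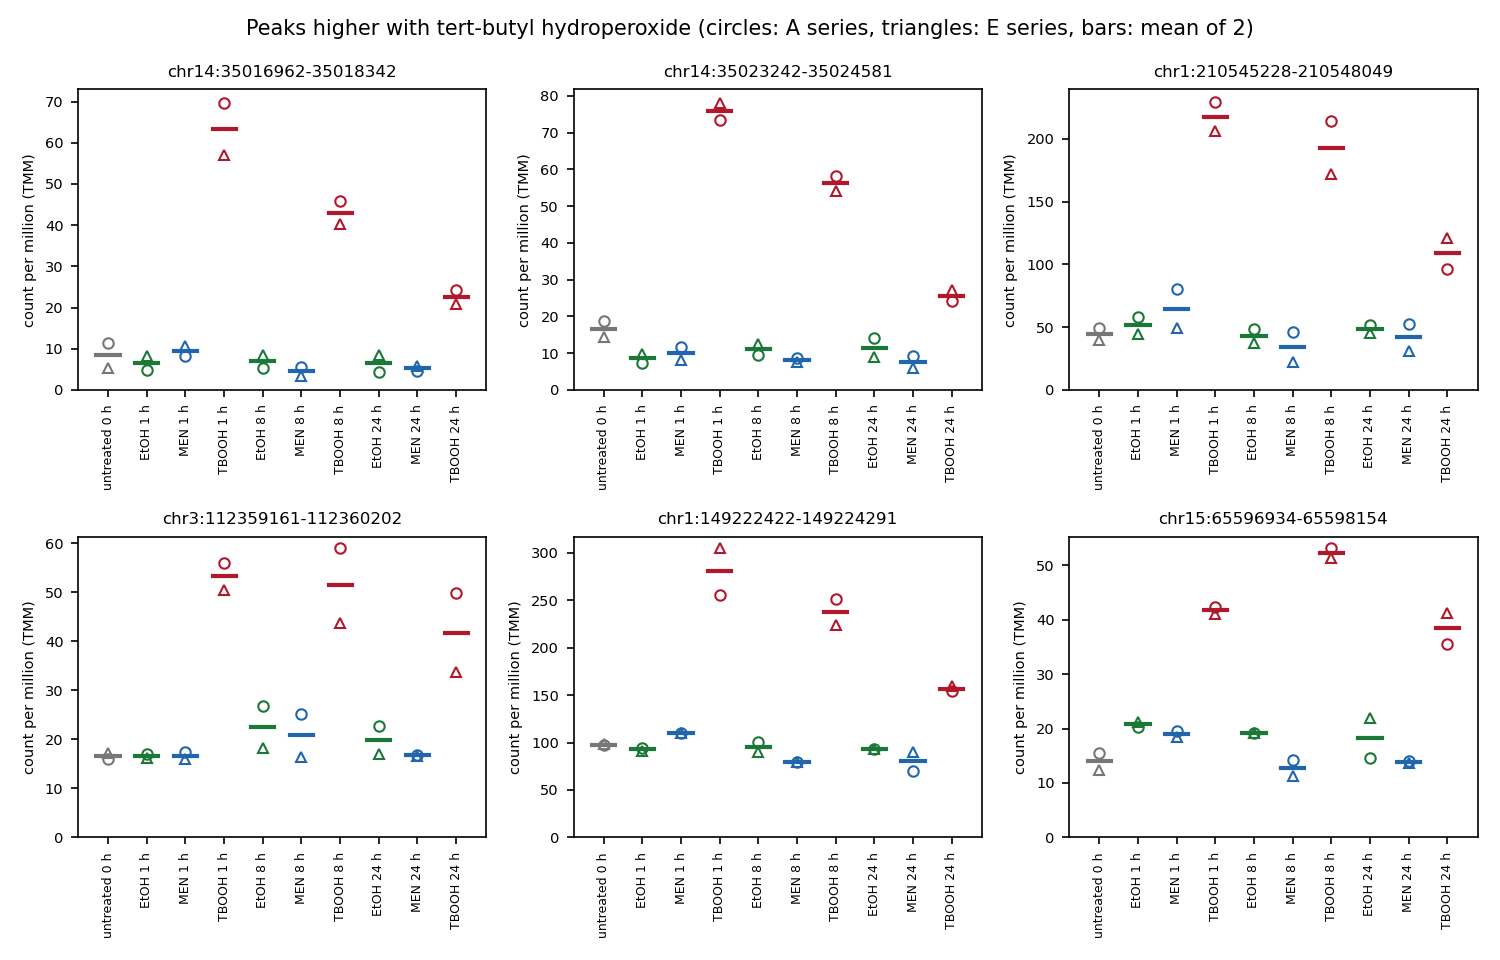
Counts per 1e6 counts (CPM, with TMM factors) of 6 peaks called with tert-butyl hydroperoxide (TBOOH) at 1 or 8 h, for each library of the 10 groups (EtOH, vehicle; MEN, menadione), with circles for the A series, triangles for the E series and bars for the mean of 2. At 14:35016962–35018342 the mean was 63.2, 43 and 22.5 CPM with TBOOH at 1, 8 and 24 h, against 6.56, 6.93 and 6.44 CPM with vehicle.

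At 8 h of TBOOH, 6 peaks rose and 0 fell, and 4 of the 6 were among the 5 called at 1 h (0.00041 from independent lists). The chromosome 14 pair stood at 43 ± 3.97 and 56.1 ± 2.91 CPM, against 6.93 ± 2.34 and 11 ± 2.25 CPM with vehicle. Their log2 fold changes were 2.66 (SE 0.37, edgeR adjusted p = 0.00024) and 2.36 (SE 0.3, edgeR adjusted p = 1e-04). The peak 1:210545228–210548049 remained high, at 193 ± 30.2 against 42.9 ± 7.7 CPM (log2 fold change 2.16, SE 0.27). Outside the rule, 1:149222422–149224291 was called again (log2 fold change 1.32, SE 0.19). First called at this time were 15:65596934–65598154, at 52.3 ± 1.19 against 19.2 ± 0.0192 CPM, and 8:129440139–129441034, at 96.5 ± 19.3 against 33.7 ± 5.11 CPM (log2 fold change 1.51, SE 0.24, edgeR adjusted p = 0.0023). At 1 h the first already stood at 41.7 ± 0.95 against 20.8 ± 0.636 CPM, and the second at 42.5 ± 1.73 against 32.9 ± 1.44 CPM. At the second, menadione had 61.7 ± 3.76 CPM at 8 h and 46.1 ± 0.728 CPM at 1 h. Whether these 2 peaks differed with TBOOH from their state at 1 h was covered by the test between times, which called 0 peaks for TBOOH.

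With the series term, 29 rises and 7 falls were called at 8 h, all 6 above among them. Its falls included 2:177710276–177711057 (log2 fold change −1.53, SE 0.33), 8:120238596–120239371 (−1.48, SE 0.29) and 6:145508457–145509183 (−1.34, SE 0.27). Without the vehicle E library 2 peaks were called without the term, and without the TBOOH A library 11.

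At 24 h of TBOOH, 4 peaks rose and 5 fell. By the rule, 5:32768015–32768790 rose from 11 ± 2.97 to 37.7 ± 7.72 CPM (log2 fold change 1.74, SE 0.33, edgeR adjusted p = 0.037). A peak on chromosome 8, 8:139965049–139965896, rose from 13.8 ± 4.01 to 44.9 ± 4.94 CPM (1.71, SE 0.31, edgeR adjusted p = 0.035). On chromosome 20, 20:58637609–58638618 fell from 78.8 ± 17.6 to 31.3 ± 1.34 CPM (log2 fold change −1.32, SE 0.24, edgeR adjusted p = 0.035). At these peaks in turn, menadione at 24 h had 27.7 ± 11.5, 21.8 ± 6.84 and 49.1 ± 8.65 CPM, none of them called. Untreated cells had 16.3 ± 1.78, 18.4 ± 0.729 and 86 ± 0.0242 CPM. The other 6, outside the rule, had mean counts of 15.4 to 47.6. Rises among them were X:57554943–57555596 (3.15, SE 0.59) and 7:17812712–17813218 (3.13, SE 0.56). TBOOH had 11.5 ± 1.12 and 16.5 ± 8.88 CPM there. Vehicle at 24 h was low at both, at 1.28 ± 0.193 and 1.81 ± 0.0427 CPM, against 2.4 ± 0.164 and 5.82 ± 1.91 CPM in untreated cells. Falls were 3:177340311–177341165 (−2.23, SE 0.42), 8:112879539–112880448 (−2.49, SE 0.45) and 6:15065680–15066519 (−2.62, SE 0.47). At 1:231827445–231827776 there were 2 counts with TBOOH and 72 with vehicle, a ratio of 0.034 (exact 95% counting interval 0.0041 to 0.13). Vehicle at 24 h was high there, at 10.8 ± 5.26 CPM against 4.59 ± 1.41 CPM in untreated cells. Of the peaks called at 24 h, all but 20:58637609–58638618 differed less from untreated cells than from vehicle. Menadione means at 24 h lay between those of vehicle and TBOOH at every one of them, but the vehicle libraries are shared and the peaks were picked for a difference from vehicle.

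The early chromosome 14 peak 14:35016962–35018342 was at 22.5 ± 2.35 CPM at 24 h, with a log2 fold change of 1.86 that missed the threshold (edgeR adjusted p = 0.1) and passed it with the series term (adjusted p = 0.0033). Its neighbour 14:35023242–35024581, at 25.6 ± 2.01 against 11.4 ± 3.62 CPM (log2 fold change 1.13, SE 0.31), missed it in both fits (edgeR adjusted p = 0.35, and 0.067 with the term). The other 5 peaks called at 1 or 8 h were all called at 24 h with the term. Their log2 fold changes in that fit were 1.17 (SE 0.19) at 1:210545228–210548049 (109 ± 17 against 48.8 ± 4.69 CPM), 1.10 (SE 0.2) at 8:129440139–129441034, 1.09 (SE 0.26) at 15:65596934–65598154, 1.07 (SE 0.25) at 3:112359161–112360202 and 0.75 (SE 0.16) at 1:149222422–149224291. Without the term none of the 5 passed in edgeR (adjusted p of 0.12 to 0.3), and DESeq2 called only 8:129440139–129441034 (adjusted p = 0.045). That term gave 101 rises and 47 falls, among the falls 7:131312329–131312936 (−2.01, SE 0.4), 1:199985781–199986632 (−1.67, SE 0.32) and 2:214040284–214040986 (−1.62, SE 0.37). With only peaks of a mean count of at least 50 in the fit, edgeR left 0 calls at 24 h (over all tested peaks, DESeq2 called 28 and edgeR gave 5095 at an unadjusted p under 0.05), and a fit of the contrasted groups alone gave 76. Nearly all calls were lost when any 1 vehicle or TBOOH library of 24 h was left out. Those fits had no series term and left 1 group with 1 series alone.

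Menadione at 1 h gave 0 calls with edgeR, with 2993 peaks at an unadjusted p under 0.05 (4.11% of those tested) and 0 calls with DESeq2. At the chromosome 14 pair raised by TBOOH, menadione libraries had 9.4 ± 1.72 and 9.97 ± 2.62 CPM. With the series term 1 peak rose, 1:198904578–198905034, from 15 ± 1.22 to 45.2 ± 9.67 CPM (log2 fold change 1.59, SE 0.27, edgeR adjusted p = 0.0038, and 0.61 without the term).

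At 8 h of menadione 1 peak was called. At 6:53480359–53481108 accessibility rose from 6.63 ± 0.331 to 32.9 ± 1.27 CPM (log2 fold change 2.31, SE 0.34, edgeR adjusted p = 0.003). TBOOH libraries had 19.8 ± 2.76 CPM there at 8 h (log2 fold change 1.57, SE 0.34, edgeR adjusted p = 0.33, and 0.021 with the series term), and menadione was not past the threshold against TBOOH (0.73, SE 0.31, edgeR adjusted p = 1). The call was lost without any 1 of the vehicle A, vehicle E, menadione A and menadione E libraries (0 calls each). DESeq2 called 13 peaks, and the fit with the series term 112 rises and 14 falls. Rises in that fit included 1:198904578–198905034 again, from 12.1 ± 2.9 to 42.2 ± 4.11 CPM (1.79, SE 0.28), and 1:177178418–177178910, from 9.42 ± 2.39 to 32.6 ± 1.02 CPM (1.77, SE 0.33). Falls at a mean count of at least 50 included 9:131418672–131419530 (−1.21, SE 0.29), 17:73305178–73305964 (−1.20, SE 0.29) and 16:85499456–85500135 (−1.17, SE 0.27). These 5 had edgeR adjusted p values of 0.063 to 0.41 without the term.

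Menadione at 24 h again gave 0 calls with edgeR (3697 peaks at an unadjusted p under 0.05) and 1 with DESeq2. The series term gave 22 rises and 6 falls. At a mean count of at least 50, the largest rises were at 9:103191630–103191983 (log2 fold change 1.94, SE 0.36), 3:17081014–17081543 (1.77, SE 0.31, from 9.46 ± 2.68 to 31.3 ± 8.89 CPM) and 2:186447823–186448727 (1.62, SE 0.32). The largest fall at that mean count was at 1:199985781–199986632, from 32.2 ± 3.1 to 7.15 ± 0.741 CPM (−2.17, SE 0.33, edgeR adjusted p = 0.00017, and 0.056 without the term). Next at that mean count came 20:52743469–52743890 (−1.08, SE 0.19) and 8:129154003–129154824 (−0.88, SE 0.18). Peaks with lower counts had larger estimates, up to 3.97 (SE 0.72) at 13:94885697–94886021 and down to −3.99 (SE 0.87) at 5:55507301–55507762.

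**Figure D2:**
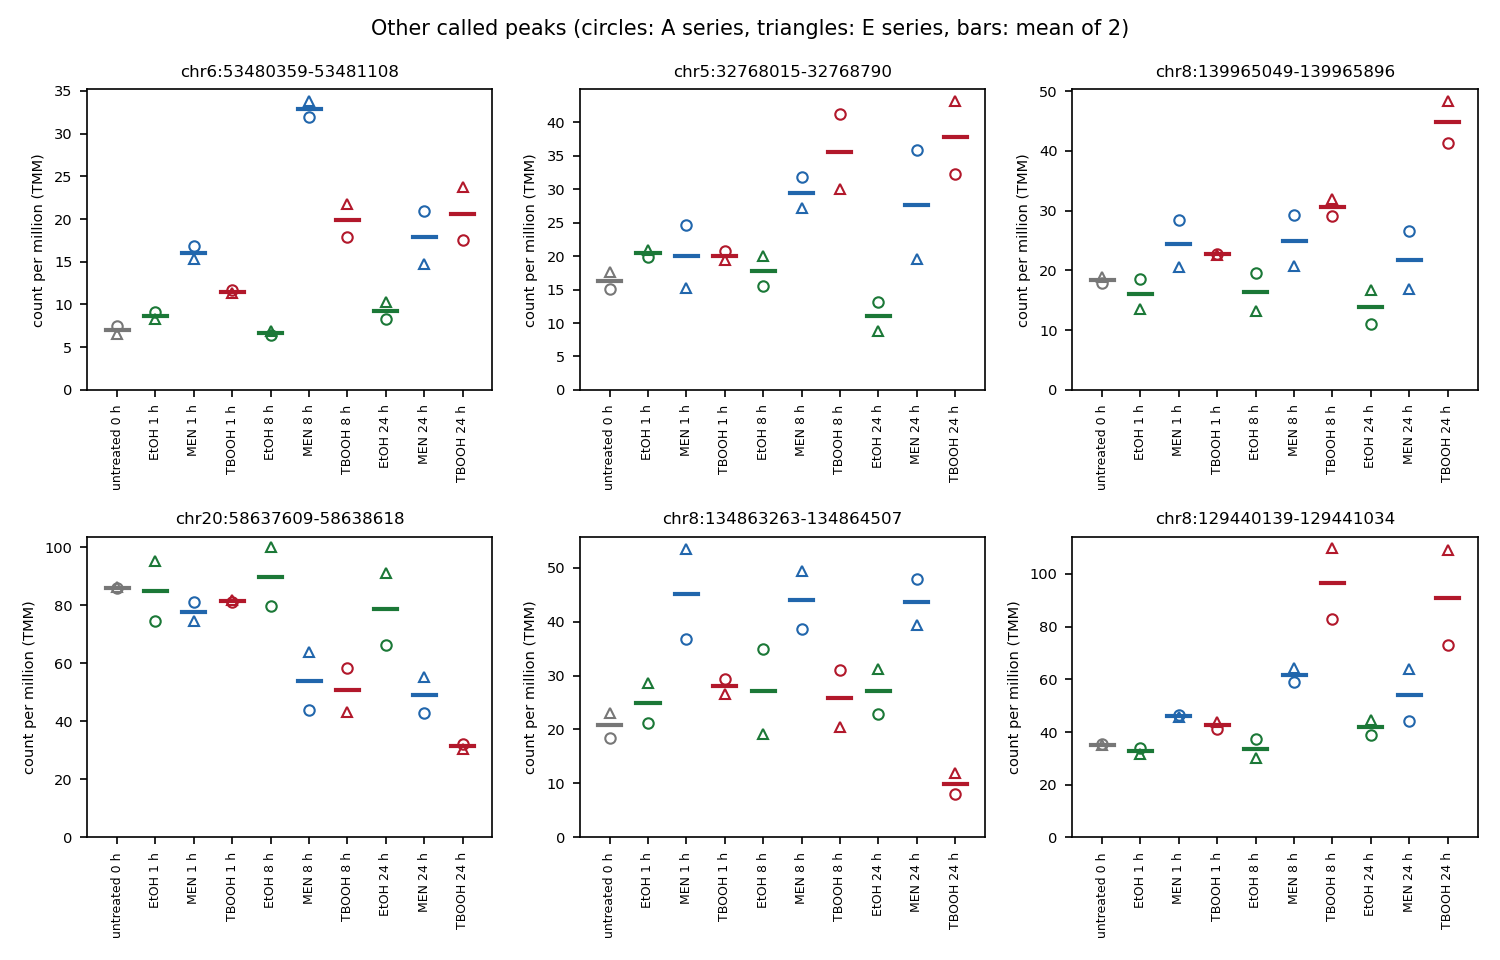
Counts per 1e6 counts (CPM, with TMM factors) of 6 further called peaks for each library of the 10 groups (EtOH, vehicle; MEN, menadione; TBOOH, tert-butyl hydroperoxide), with circles for the A series, triangles for the E series and bars for the mean of 2. At 6:53480359–53481108 menadione at 8 h had 32.9 CPM against 6.63 CPM with vehicle, and at 20:58637609–58638618 TBOOH at 24 h had 31.3 CPM against 78.8 CPM.

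The oxidants were compared directly at each time at the doses given (10 µM menadione and 80 µM TBOOH), which differ. At 1 h, 5 peaks were lower with menadione and 0 higher, and they were the 5 peaks raised by TBOOH. Log2 differences were −2.90 (SE 0.31) and −2.76 (SE 0.36) at the chromosome 14 pair, −1.74 (SE 0.27) at 1:210545228–210548049, −1.67 (SE 0.29) at 3:112359161–112360202 and −1.35 (SE 0.19) at 1:149222422–149224291. At 8 h, 7 peaks were lower with menadione and 0 higher. By the rule these were 14:35016962–35018342 (−3.18, SE 0.4), 14:35023242–35024581 (−2.78, SE 0.32), 1:210545228–210548049 (−2.46, SE 0.28), 15:65596934–65598154 (−2.01, SE 0.28) and 1:149222422–149224291 (−1.58, SE 0.19). Outside it were 12:120728340–120731100 (−1.31, SE 0.24) and 1:11968133–11969578 (−1.52, SE 0.27). At 24 h, 8:134863263–134864507 was higher with menadione, at 43.6 ± 5.97 against 9.97 ± 2.68 CPM (2.17, SE 0.33, edgeR adjusted p = 0.0063).

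The series term gave 0 higher and 6 lower at 1 h, 3 and 16 at 8 h, and 2 and 9 at 24 h (4 and 9 with loess offsets as well). Among the 3 higher with menadione at 8 h in that fit were 17:70657326–70658203 (1.63, SE 0.3) and 1:198904578–198905034 (1.59, SE 0.28). At 24 h, 6 of the 9 lower with menadione were peaks called with TBOOH at 1 or 8 h: 14:35016962–35018342 (−2.13, SE 0.37), 14:35023242–35024581 (−1.72, SE 0.31), 15:65596934–65598154 (−1.46, SE 0.27), 1:210545228–210548049 (−1.40, SE 0.19), 3:112359161–112360202 (−1.32, SE 0.25) and 1:149222422–149224291 (−0.98, SE 0.16). Without the term edgeR gave these 6 adjusted p of 0.11 to 0.32, and DESeq2 called 4 of them (adjusted p of 0.0063 to 0.022). Left-out libraries moved the counts without the term: at 1 h to 2 without menadione E and 3 without either TBOOH library, at 8 h to 4 without menadione E, and at 24 h to 0 without menadione A, TBOOH A or TBOOH E. For the remaining peaks a 2-fold difference between the oxidants was excluded by the 95% interval in 26.9%, 26.6% and 24.9% of tested peaks at 1, 8 and 24 h, so a missed threshold does not show that the oxidants acted alike.

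Vehicle against untreated cells, the background of ethanol and time in culture, gave 0 calls at 1, 8 and 24 h with edgeR, DESeq2 and the series term. At an unadjusted p under 0.05 there were 2838, 2126 and 1793 peaks with edgeR (3.9%, 2.92% and 2.46% of those tested). Without the vehicle A library at 1 h, 1 peak was called at that time.

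Changes of the oxidant effect between times were tested for each peak. For menadione 0 peaks were called with edgeR and DESeq2 (1674 at an unadjusted p under 0.05 with edgeR) and 1 with the series term. For TBOOH 0 were called by all 3 (2440 at an unadjusted p under 0.05 with edgeR). The decline at the chromosome 14 peaks from 1 to 24 h was thus not past this test.

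Effects of the oxidants went in the same direction more often than simulated unchanged groups that shared the vehicle libraries. Across peaks, which are not independent replicates, log2 fold changes of menadione and TBOOH correlated with r = 0.6, 0.57 and 0.54 at 1, 8 and 24 h, against 0.475, 0.472 and 0.48 in the simulation. The covariance was 0.205, 0.192 and 0.189 against 0.115, 0.112 and 0.123, a difference of 0.09, 0.08 and 0.066. The sign was shared by 72.6%, 71.1% and 69.1% of peaks, against 65.9%, 65.8% and 66%. Each vehicle group has 2 libraries and cannot be split into groups of 2, so part of the excess may come from the shared controls. Within the A series r was 0.55, 0.5 and 0.51, against a mean of 0.48, 0.48 and 0.48 in unchanged simulated data. Within the E series it was 0.58, 0.52 and 0.47, against 0.46, 0.45 and 0.47, so at 24 h the E series alone showed no excess. Without the A library of menadione r was 0.29, 0.33 and 0.33, and without that of TBOOH 0.36, 0.37 and 0.34, while without the A library of vehicle it was 0.87, 0.82 and 0.76. These fits had no series term and left a group with 1 series alone, so the difference between series entered the values. No unchanged data were simulated with a library missing, so these values cannot be set beside those of the full design.

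In the calls with the series term, 14 rises were shared by the oxidants at 8 h (0.045 from independent lists). At 24 h they shared 10 rises (0.031) and 4 falls (0.0039). Unchanged simulated groups that shared the vehicle libraries gave 0 shared calls over 10 data sets. When their strongest peaks were taken as lists of the same sizes, 1 to 6 rises were shared at 8 h, 1 to 6 rises at 24 h and 0 to 1 falls at 24 h. These simulated groups, too, lacked the shift with mean accessibility. One oxidant at 2 times shares no libraries, and r was then 0.21, 0.14 and 0.24 for menadione at 1 and 8, 1 and 24, and 8 and 24 h, and 0.18, 0.15 and 0.22 for TBOOH. Within the A series these were 0.12, 0.15, 0.21, 0.095, 0.068 and 0.082, and within the E series 0.14, 0.037, 0.058, 0.17, 0.069 and 0.16. These r values moved when single libraries were left out, most often an A oxidant library or an E vehicle library. Such a fit had no series term and set groups of unlike series against each other, so the values do not show the weight of a library alone. For menadione at 1 and 8 h r was 0.064 without vehicle 1 h E, 0.039 without menadione 1 h A, 0.12 without vehicle 8 h E and 0.095 without menadione 8 h A. At 1 and 24 h it was 0.06 without vehicle 1 h E, 0.045 without menadione 1 h A and 0.01 without menadione 24 h A, and at 8 and 24 h 0.14 without menadione 8 h A and 0.067 without menadione 24 h A. For TBOOH at 1 and 8 h it was 0.096 without vehicle 1 h E, 0.079 without TBOOH 1 h A, 0.043 without vehicle 8 h E and 0.06 without TBOOH 8 h A. At 1 and 24 h it was 0.081 without vehicle 1 h E and 0.076 without either TBOOH A library, and at 8 and 24 h 0.14 without vehicle 8 h E. With the series term, 14 rises were shared by TBOOH at 8 and 24 h (0.04 from independent lists) and 8 by menadione at 8 and 24 h (0.034).

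Called peaks were more often in the highest of 5 accessibility classes than tested peaks as a whole, in each of the 8 lists tested. No comparison had 10 calls in a direction without the series term, so location was tested on the calls made with it. Of 112 peaks that rose with menadione at 8 h, 61 (54.5%) were IDR peaks in all 10 conditions, against 25.4% of tested peaks (Fisher's exact test, adjusted p = 2.6e-09). Of the 101 that rose with TBOOH at 24 h, 54 (53.5%) were (Fisher's exact test, adjusted p = 3.6e-08). This share was not past the threshold for the menadione rises at 24 h (adjusted p = 0.21) and the falls with menadione at 8 h (0.11) and TBOOH at 1 h (1) and 24 h (0.16), in Fisher's exact test. Peaks of the highest accessibility class made up 44.6% and 40.6% of the rises with menadione at 8 h and TBOOH at 24 h, against 20% of tested peaks (Fisher's exact test, adjusted p = 3.8e-08 and 1.2e-05). Peaks wider than the median made up 74.1% and 81.2% of these rises, and this excess was past the threshold in every list but the TBOOH falls at 1 h (81.8%, Fisher's exact test, adjusted p = 0.083). Power favours calls in such peaks: with the term, 94.1% and 90.9% of simulated 4-fold changes were recovered at a mean count of at least 50 in these comparisons, against 50% and 47% overall.

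Chromosome 8 held 17 of the 112 menadione rises at 8 h (15.2%, against 6.12% in random lists matched on mean count, adjusted p = 0.0013) and 15 of the 101 TBOOH rises at 24 h (14.9% against 6.2%, adjusted p = 0.0081). Chromosome 6 held 8 of the 47 TBOOH falls at 24 h (17% against 5.83%, adjusted p = 0.023). Some lists of rises lay close together. Of the 29 TBOOH rises at 8 h, 8 had another within 100 kb (27.6% against 0.688%, adjusted p = 0.00072), and of the 112 menadione rises at 8 h, 10 (8.93% against 1.7%, adjusted p = 0.011). The other lists showed no excess past the threshold: 6 of 101 TBOOH rises at 24 h (adjusted p = 0.14), 2 of 17 at 1 h (adjusted p = 0.11), 0 of 22 menadione rises at 24 h, and the lists of falls (adjusted p of 0.49 to 1).

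Several of these neighbours were on the long arm of chromosome 20, which is known to carry amplified segments in this line. With menadione at 8 h, the log2 fold change was 0.71 (SE 0.15) at 20:52522441–52523355, 0.99 (SE 0.16) at 20:52543080–52543961, 0.67 (SE 0.11) at 20:52739814–52740698, 0.96 (SE 0.17) at 20:52749052–52749690, 0.70 (SE 0.13) at 20:52883778–52884748 and 1.31 (SE 0.22) at 20:52961775–52962371. The mean count at 20:52739814–52740698 was 3820. With TBOOH at 24 h 4 of these 6 rose as well, by 0.75, 0.58, 1.08 and 0.62 at 20:52522441–52523355, 20:52739814–52740698, 20:52749052–52749690 and 20:52883778–52884748. Between 20:52739814–52740698 and 20:52749052–52749690, the peak 20:52743469–52743890 fell with menadione at 24 h (−1.08, SE 0.19) and with TBOOH at 24 h (−1.21, SE 0.2). On chromosome 15, 15:65588071–65589233 rose with TBOOH at 8 h (1.36, SE 0.28) beside 15:65596934–65598154 (1.44, SE 0.24). All of these calls were made with the series term, and without it 15:65596934–65598154 alone was past the threshold.

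The precision limits what the low counts mean. A 2-fold change was excluded by the 95% interval in 24.6% of peaks, pooled over the 6 oxidant comparisons, and, in the same fit, in 70.8% of the 19411 peaks with a mean count of at least 50. By comparison the share ran from 22.2% (TBOOH, 1 h) to 27.2% (menadione, 1 h). Different peaks called in any of the 6 comparisons numbered 17 (0.023% of those tested), and 304 (0.42%) with the series term.

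Libraries separated by series, and oxidant from vehicle libraries. On the first principal component (15.9% of the variance) the A library lay above the E library in 10 of 10 groups, and the oxidant library above the vehicle library of the same time and series in 12 of 12 pairs. On the second (9.06%) the oxidant library was lower in 11 of 12 pairs. On the first, the untreated E library lay at −27.9, and vehicle E libraries at −127, −100 and −44 (1, 8 and 24 h). Menadione E libraries lay at −50.1, 18.1 and −35.2, and TBOOH E libraries at 0.658, −20.7 and 20.3. In the E series at 1 and 8 h, much of the gap was thus a move of vehicle away from untreated. In the A series untreated lay at −6.21, vehicle at 14.3, 12.7 and −10.3, and the oxidants at 35.9 to 79. Among peaks with a mean count of at least 50, the SD over peaks of the log2 ratio was 0.36 to 0.53 between the A and E libraries of a group (median 0.473), and 0.33 to 0.56 between oxidant and vehicle within a series (median 0.4). At the median, the spread between oxidant and vehicle was no larger than that between the 2 libraries of a group. The spread within a group also holds the difference between series, so the values do not set treatment against replicate spread alone. Across all tested peaks, the effect in the A series correlated with that in the E series with r = 0.13, 0.23 and 0.13 for menadione at 1, 8 and 24 h, and 0.17, 0.18 and 0.18 for TBOOH. Among peaks with a mean count of at least 50, r was 0.21, 0.38 and 0.19 for menadione and 0.27, 0.3 and 0.34 for TBOOH.

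**Figure D3:**
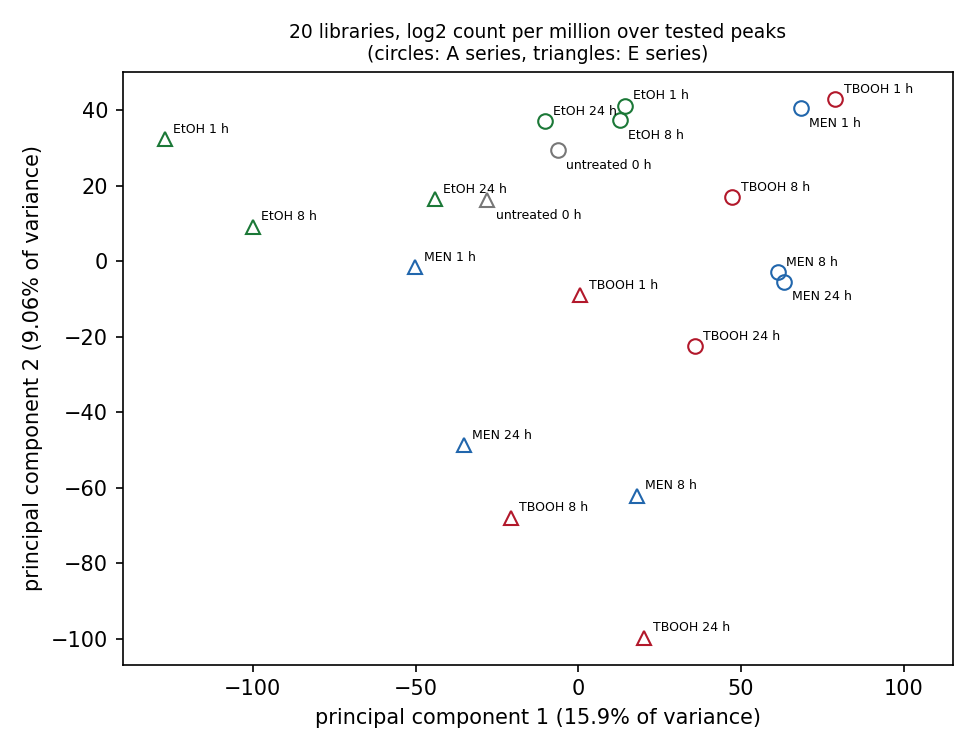
First and second principal component (15.9% and 9.06% of the variance) of log2 CPM over the tested peaks for the 20 libraries, with circles for the A series, triangles for the E series, grey for untreated, green for vehicle (EtOH), blue for menadione (MEN) and red for tert-butyl hydroperoxide (TBOOH). The oxidant library lies to the right of the vehicle library of its time and series in 12 of 12 pairs, and the A library to the right of the E library in 10 of 10 groups.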

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

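The peak below came from an alternative chosen after seeing the data, the fit with library series as a term. The effect of menadione differed between times at 1:197221789–197222492 in that fit (edgeR adjusted p = 0.044), and not without the term (adjusted p = 1). Its log2 fold change against vehicle was 1.13 (SE 0.38) at 1 h, −0.40 (SE 0.38) at 8 h and −2.15 (SE 0.42) at 24 h, at a mean count of 41.8. It is the single peak called among 72830. The same test with the term called 4 peaks over 10 simulated data sets with no change, and 0 without the term, so a single call is not beyond chance.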

How the results depend on the processing

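Chosen after seeing the data were the series term, alone or with loess offsets, every alternative for the correlations, the excluded share and the chromosome medians, and everything averaged over time. The tests by replicate number were not run because the columns carry none. No paired analysis was possible because the columns carry no replicate number; the letters stood in for it. Gene lists, motif lists and corrections for base composition were not run for want of a genome and gene names of hg19. In each case below the cause was not tested unless a smaller number of peaks or libraries gives it.

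The 34 named calls kept direction in every alternative (0 reversed). They stayed past the threshold in 34 of 34 with DESeq2, DESeq2 size factors, library totals, no filter and the series term with or without loess offsets, in 33 of 34 with loess offsets, in 24 of 28 at a mean count of at least 50 and in 29 of 34 in fits of the contrasted groups. With 1 library left out, 63 of 136 stayed and 73 did not; the lone library is then assumed to vary like those of other groups.

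Counts of calls below are for menadione at 1, 8 and 24 h, then TBOOH at 1, 8 and 24 h, then menadione against TBOOH at 1, 8 and 24 h. The replicate block by library series gave 1, 126, 28, 28, 36, 148, 6, 19 and 11 calls, against 0, 1, 0, 5, 6, 9, 5, 7 and 1 without it. With loess offsets as well it gave 1, 183, 48, 33, 43, 172, 10, 21 and 13. By time the block gave 1 for menadione and, with loess offsets, 2 for menadione and 1 for TBOOH. The block changed no call of vehicle against untreated. Menadione at 8 h went to 2 calls with library totals, 5 with loess offsets, 5 at a mean count of at least 50, 2 in the contrasted groups, 13 with DESeq2 and 2 at adjusted p under 0.1. Menadione at 24 h had 1 in the contrasted groups, 1 with DESeq2 and 2 at adjusted p under 0.1. TBOOH had 8 with DESeq2 at 1 h, and at 24 h 0 at a mean count of at least 50, 76 in the contrasted groups, 28 with DESeq2 and 18 at adjusted p under 0.1. Its rises and falls at 24 h were 4 and 7 with DESeq2 size factors and 5 and 8 with library totals or loess offsets. Menadione against TBOOH had 2 in the contrasted groups at 1 h, 12 at 8 h with 15 by DESeq2 and 11 at adjusted p under 0.1, and 5 by DESeq2 at 24 h.

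The share of peaks with a 2-fold change excluded (24.6%) was 69.8% in a fit of only the peaks with a mean count of at least 50 (70.8% for such peaks in the fit of all tested peaks), 31.5% with the block, 31.7% with loess offsets added, and 2.4% for a 1.5-fold bound. Averaged over time, 143 and 129 peaks were called with no replicate block, and 83 and 2 with log2 library total as a term.

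Correlations of effects are for menadione and TBOOH at 1, 8 and 24 h, then menadione at 1 and 8, 1 and 24, and 8 and 24 h, then TBOOH likewise. Among peaks above the median mean count r was 0.66, 0.63, 0.59, 0.37, 0.25, 0.38, 0.32, 0.26 and 0.38, and at a mean count of at least 50 it was 0.69, 0.66, 0.62, 0.45, 0.32, 0.45, 0.38, 0.33 and 0.47. In series A alone it was 0.55, 0.5, 0.51, 0.12, 0.15, 0.21, 0.095, 0.068 and 0.082, and in series E alone 0.58, 0.52, 0.47, 0.14, 0.037, 0.058, 0.17, 0.069 and 0.16. For TBOOH at 1 and 24 h it was 0.15 with library totals and the block, and 0.14 with loess offsets, no filter, or the block with loess offsets. Of all 156 alternatives for r, 0 turned the sign.

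Without 1 library, calls ranged from 0 to 0 for menadione at 8 h, 3 to 30, 2 to 11 and 0 to 1 for TBOOH at 1, 8 and 24 h, 2 to 4, 4 to 7 and 0 to 1 for menadione against TBOOH, 0 to 1 for vehicle against untreated at 1 h, and 778 to 2912 and 315 to 1519 for the averages. The excluded share was 19.6 to 23.6%, and r was 0.29 to 0.87, 0.33 to 0.82, 0.33 to 0.76, 0.039 to 0.25, 0.01 to 0.18, 0.067 to 0.28, 0.043 to 0.24, 0.076 to 0.16 and 0.14 to 0.2. Apart from the averages, these fits had no series term, so the difference between series entered the groups left with 1 library.

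Within the highest accessibility class the median log2 fold change turned negative on chromosomes 2 (−0.055), 5 (−0.03), 7 (−0.043), 13 (−0.039), 18 (−0.066) and X (−0.029). That class as a whole had medians of −0.12 to −0.048 in the 6 comparisons, so a turn below 0 does not by itself bear on differences between chromosomes. Chromosomes 5, 7, 13 and X lay above this range. Chromosomes 2 and 18 lay within it. Set beside the class in the same comparison, chromosome 2 lay above it except with menadione at 24 h (−0.075 against −0.073). Chromosome 18 lay below it at 1 h with menadione (−0.066 against −0.054) and TBOOH (−0.17 against −0.12), and above it in the other comparisons. Depth limits the low peaks most.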

Other observations

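Everything averaged over the 3 times was chosen after seeing the data, as were the tests of scaling and of a common source at the TBOOH peaks, the loess test of the chromosomes and the count of other splits. The test of a common source by simulation replaced a chi-square form after the values of that form were seen, because 1 gain was too uncertain to divide by. The bound for the depth test was set before its values, but the demand that it be passed by more than the quartiles was added after them. Averaged over 1, 8 and 24 h with library series as a term (6 against 6 libraries), menadione raised 1261 peaks and lowered 809 of 72239 tested. Of these, 476 changed at least 2-fold, 420 up and 56 down. Its largest rises at a mean count of at least 50 were 1:198904578–198905034, from 13.3 ± 1.98 to 37.7 ± 11.5 CPM (SD, n = 6; log2 fold change 1.48, SE 0.15), 3:4928702–4929309, from 9.76 ± 1.94 to 26.1 ± 4.34 CPM (1.40, SE 0.17), and 6:53480359–53481108, from 8.2 ± 1.43 to 22.3 ± 8.54 CPM (1.39, SE 0.2). TBOOH, averaged in the same way, raised 762 peaks and lowered 699 of 72155 tested, 335 of them at least 2-fold. Among its rises at a mean count of at least 50 was 3:112359161–112360202, from 19.7 ± 4.15 to 48.8 ± 9.1 CPM (1.29, SE 0.14), where the log2 fold change with menadione was −0.12 (SE 0.16).

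Both oxidants lowered 1:199985781–199986632 (log2 fold change −1.12 with menadione and −0.97 with TBOOH), 6:151954477–151955384 (−0.89 and −0.92) and 5:128513118–128513886 (−0.83 and −1.17). On chromosome 6, 6:151937172–151938276 lies near the second of these and fell with both as well (−0.69 with menadione, edgeR adjusted p = 0.0013, and −0.93 with TBOOH, edgeR adjusted p = 0.00058). Among 71684 peaks tested in both, 367 rose with both (13.3 from independent lists), 233 fell with both (7.89), and 2 went opposite ways. The oxidants share their vehicle libraries, and lists of the same sizes from unchanged simulated data shared 124 to 147 rises and 80 to 105 falls over 10 data sets, so part of this overlap comes from those libraries. The simulated data lacked the shift with mean accessibility that the oxidant comparisons shared.

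The averaged effects rest on the fit: without the series term 143 peaks (128 up, 15 down) were called for menadione and 129 (101 up, 28 down) for TBOOH, and loess offsets moved the split to 1351 up and 379 down, and 960 up and 375 down. Other splits of the 12 libraries were drawn without regard to time and series. For menadione 1 of 40 gave as many calls (the real one, 2070, highest other 1391, a split that kept 5 of the 6 menadione libraries together). For TBOOH 1 of 40 did (the real one, 1461, highest other 21). The real split was balanced over time and series and ran with lower depth, and the others were not held to this. These counts therefore do not settle chance. As to a shift of the vehicle libraries, the untreated libraries lay at a median of 0.32 of the way from vehicle to TBOOH (A 0.12, E 0.47). For menadione this was 0.34 (A 0.13, E 0.5). The bound set beforehand, under 0.5 in both untreated libraries, was passed for TBOOH and missed for menadione by 1 library. The values were nearly equal, and the peaks had been picked for a difference from vehicle. The 2 oxidants are thus not set apart, and a vehicle part stays open for both. Lower depth of the oxidant libraries cannot be told apart from the treatment, because with library total as a term the log2 fold changes kept a median of 0.83 (quartiles 0.67 and 0.99) and 0.76 (0.42 and 1.1) of their size but 83 and 2 peaks were called. Single libraries moved the counts by over 1.5 times: for menadione to 951 and 899 without vehicle 8 h A and E, 1187 and 1039 without menadione 8 h A and E, 778 without vehicle 24 h A and 1159 without menadione 24 h A, and for TBOOH to 809 without vehicle 1 h E, 910 without TBOOH 1 h A, 335 without vehicle 8 h E, 443 without TBOOH 8 h E, 315 without vehicle 24 h A and 531 without TBOOH 24 h E.

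The peaks raised by TBOOH at 1 h, and lower with menadione in the direct comparison, form the second pattern. As to scaling, the lowest log2 fold change of the 5 over 3 other scalings was 1.58. The TMM factors ran only from 0.966 to 1.03, so another global scaling could change little, and this says little about other technical causes. A second candidate is 1 source of reads, such as an amplified or repeated sequence, spread over similar regions, whose gains would keep 1 ratio between 1 and 24 h. Whether such regions were filtered is not known. The peak 1:149222422–149224291 lies toward the centromere on the long arm of chromosome 1, a part rich in duplicated sequence. Over the 7 peaks called at 1 or 8 h, 30 of 10000 sets simulated with 1 ratio misfitted as much, but this rests on 8:129440139–129441034, with gains of 9.69 (SE 7.4), 62.8 (SE 13) and 48.9 (SE 13) CPM at 1, 8 and 24 h. For the other 6, first tested before the 7, 1387 of 10000 sets did at a common ratio of 32.8%. A common source thus stays open for them beside a response to the peroxide at each region, which is the hypothesis the design offers. Such a source would itself have to gain reads with TBOOH and not with menadione. The question is therefore where the reads arose.

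Median log2 fold changes followed the chromosome: they were below 0 in all 6 oxidant comparisons on chromosomes 15, 16, 17, 19, 21 and 22 (−0.35 to −0.13 on 22) and above 0 in all 6 on chromosomes 2, 3, 4, 5, 7, 8, 13, 18 and X (0.08 to 0.16 on 4). A trend with mean accessibility is argued against as the whole cause, since 14 of the 15 kept their direction in at least 5 comparisons with loess offsets. Within the highest accessibility class, however, chromosome 18 lay below the class as a whole with both oxidants at 1 h, and chromosome 2 slightly so with menadione at 24 h. A shift of the vehicle libraries alone is argued against by the untreated libraries, against which 15 of 15 kept the direction in at least 4 of the 6 oxidant groups, but on 11 of the 15 the vehicle libraries lay on the opposite side of untreated in at least 2 of 3 groups, so a vehicle part of the trend stays open. Chromosomes 19 and 22 are rich in genes and in G and C, and base composition of the fragments may be the source, which could not be tested with 0 genome sequences of this build. That and the lower depth of the oxidant libraries stay open beside a treatment effect.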
